A study of Mus musculus with 6 samples.

How the data were processed

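Polyadenylated RNA from inguinal white adipose tissue in 6 mouse samples, 3 controls and 3 with Foxp4 deleted by Adipoq-Cre, was made into libraries with a stranded mRNA kit and sequenced on an Illumina HiSeq instrument, per the labels' protocols. The submitters' processing notes name cutadapt, HISAT2 and HTSeq and the mouse build mm10. Versions, annotation and settings, the strand setting of the counting among them, are not given in the sources used here. Without a stated strand setting, reads of genes that overlap on opposite strands may not have been kept apart. The labels do not say whether each sample was a separate mouse or a pool, so p-values measure only the spread between these samples. They give no sex, batch, order of handling or hour of dissection.

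The deposited values are FPKM per gene, 1 column per sample, in a table of 21936 rows. The unit was read from the values: the deposited FPKM times the merged exon length of the gene (GENCODE M21 annotation of the same build) and 1 scale factor per library, found from the values themselves, was a whole number of reads, within 0.05, for 97.96 to 98.12% of values up to 50 reads. Whether single reads or pairs were counted is not stated. The table holds 21900 distinct symbols, and 36 further rows that repeat a symbol, with mean FPKM up to 2.61, were left out in favour of the higher row. An exon length was found for 21398 symbols, nearly all protein-coding (21364). Recovered reads of 21269 genes summed to between 13132069 and 15957754 per library, and 129 genes with a low value that was not whole were left out of them. At this depth 1 read on a gene with 1 kilobase of exon is worth 0.062 to 0.075 FPKM. The 10 most abundant genes took 20.0 to 24.5% of reads, Scd1 alone 6.26 to 9.81%, and genes of the mitochondrial genome 7.07 to 10.5%. A total of 5028 genes were listed at 0 in every library. No 2 libraries agreed within counting noise: the chi-square per degree of freedom between any 2 was at least 9.28. It was 9.28 to 20.6 between knockouts, 30.1 to 45.4 between controls and 21.5 to 62.7 between a control and a knockout. The controls thus differed more among themselves than the knockouts did.

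The design written before the data were examined assumed counts and named limma as the test for a normalized unit. Because the values were FPKM, genes were tested with limma (version 3.58.1 in R 4.3.3) with a mean-variance trend on log2(FPKM + 1), genotype as the only term and all 6 libraries in the fit. A fold change on this scale understates that of genes with low values, so group means are given beside it. Genes with a mean of at least 1 FPKM in either group entered the test (10787 genes), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. An exact test of 3 against 3 cannot give a two-sided p below 0.10. Lower values in limma rest on its model of normally distributed errors, with the spread shared across genes.

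A total of 32 gene lists of pathways, cell types and sex-linked genes were fixed before the data were examined, and 29 with at least 3 tested members entered the set tests. The set test was camera with a preset correlation of 0.01, with camera at an estimated correlation and the directional test of fry beside it, all adjusted over the 29 lists. Counts of members "adjusted over the list alone" use the same limma p-values with the Benjamini-Hochberg method applied within the list. Some members stand in more than 1 list. Named genes followed a rule fixed at the same time: Foxp4; up to 10 genes per direction with the largest fold among those past the threshold with non-overlapping groups; a panel of 10 adipose genes; and for each list up to 4 members with the smallest unadjusted p, or for cell types up to 3 with the highest mean. Genes chosen after values were seen are mt-Co1, Gapdh, Trem2, Atp2a1 and Ckmt2 in the report, the muscle markers Mylpf and Ckm in its plot, and the genes so described in the closing section. One gene that the rule would name is not reported here. Positions are those of GENCODE M21.

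The test was tried on simulated data made from the real means and residual spreads of the 10787 genes, with 200 genes changed per run in 20 runs. At an adjusted p of 0.05 limma recovered 33.8% of genes changed 1.5-fold, 66.5% of those changed 2-fold and 89.8% of those changed 4-fold, with 8.05 unchanged genes called per run on average. Each gene's spread, estimated with 4 residual degrees of freedom, was taken as its true spread. These shares can therefore overstate the power in the real data. Camera called a list of 20 genes shifted by 0.5 on the log2 scale in 20 of 20 runs and an unshifted list in 0 of 20, with genes simulated as independent.

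Alternatives were a pseudocount of 0.1, no filter, the replicate number as a block, leaving out each library in turn, a fold change of at least 1.5, the 2 other set tests, and leaving out the genes of the lymph node, skeletal muscle, epithelial and erythroid lists. Added after the data were seen were median-of-ratios and upper-quartile scaling of the FPKM, a filter at 5 FPKM in at least 3 libraries, limma's voom on the recovered reads, an adjusted p of 0.10, and the creatine and calcium cycling list without Atp2a1 and Ckmt2. Planned count models were not run, and limma's voom was the one model run on recovered reads. Statistics were computed in R, and tables and plots were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.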

Results

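RNA was sequenced from the inguinal white adipose tissue, the subcutaneous fat pad of the groin, of 6 samples from C57BL/6 mice aged 2 months that had spent 7 days at 4 °C after housing at 22 °C. Cold exposure of this kind recruits thermogenic (beige) adipocytes in this depot. In 3 knockout samples Foxp4, a forkhead transcription factor, had been deleted with a Cre recombinase driven by the adiponectin (Adipoq) promoter, which is active in mature adipocytes. The 3 control samples are labelled only as carrying the floxed gene. The single comparison of the design asks which transcripts differ in cold-exposed inguinal fat when adipocytes lack Foxp4. By the labels the Cre driver and the loss of Foxp4 go together, so their effects cannot be told apart in any gene or list below. The libraries held between 13132069 and 15957754 recovered reads on annotated genes, and between 10405 and 10902 genes per library reached 1 FPKM. The Y-linked gene Ddx3y was present in all 6 libraries, at a mean of 25.8 FPKM in controls and 23.0 FPKM in knockouts.

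Foxp4 (chromosome 17, 47867133 to 47924645, minus strand, mm10) stood at 5.76, 4.01 and 4.62 FPKM in the controls and at 1.92, 1.71 and 1.64 FPKM in the knockouts. The control mean of 4.80 ± 0.89 FPKM (SD, n = 3) was 2.73 times the knockout mean of 1.76 ± 0.15 FPKM (SD, n = 3), and the 2 groups did not overlap. These values rest on 289 to 400 reads per control library and 112 to 140 reads per knockout library. The fitted log2 fold change was -1.06 (SE 0.12), with an adjusted p of 0.070 in limma, which missed the threshold of 0.05. The whole-tissue RNA also holds transcripts of cells in which the Adipoq promoter is not active, and gene-level values do not show which exons remained. Foxp1, a related factor of the same family, stood at 1.69 ± 0.19 FPKM in controls and 1.44 ± 0.21 FPKM in knockouts (SD, n = 3).

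Of 10787 genes tested, 1 passed an adjusted p of 0.05 in limma. This was Mb (chromosome 15, 77015487 to 77050670, minus strand), which encodes the oxygen-binding protein myoglobin. Mb rose from 1.03 ± 0.23 FPKM in controls to 10.4 ± 3.31 FPKM in knockouts (SD, n = 3), with 20 to 27 reads per control library and 180 to 281 per knockout library. Its fitted log2 fold change was 2.46 (SE 0.20, 95% interval 2.00 to 2.93), with an adjusted p of 0.042 in limma. The call was lost without control replicate 1 (adjusted p = 0.12), without control replicate 2 (0.085) and without knockout replicate 1 (0.17), in fits in which the log2 fold change lay between 2.43 and 2.55. No gene was called lower. Below that threshold the groups were apart in many genes: 2601 had an unadjusted p under 0.05, where chance gives 539, with 753 higher and 1848 lower in knockouts. The median log2 fold change over all genes tested was -0.082, and -0.0022 after median-of-ratios scaling, so the split by direction depends on the scaling. The 3 knockouts all lay on one side of the 3 controls in 3362 genes (31.2%), against the 10% that chance gives for groups of this size. At an adjusted p of 0.10, a threshold chosen after the data were seen, 591 genes passed, 191 higher and 400 lower, and after median-of-ratios scaling the split was 483 higher and 212 lower. With all 6 libraries that count was 3 without a filter and 0 with the replicate number as a block. It also hung on single libraries: it was 0 without control replicate 1 or knockout replicate 1, 1 without knockout replicate 2, 19 without knockout replicate 3, 247 without control replicate 2 and 311 without control replicate 3. The count at an unadjusted p of 0.05 was 1501 without knockout replicate 2.

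**Figure D1:**
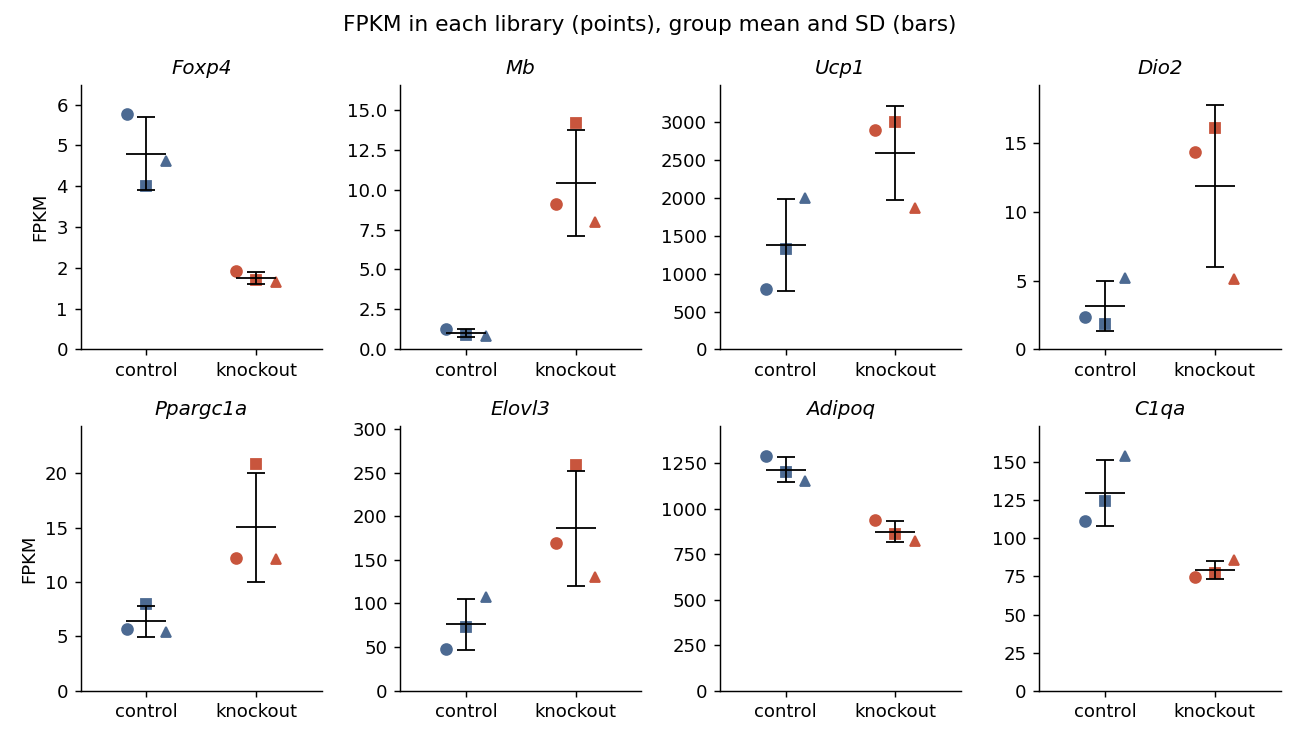
FPKM (y axes, linear and starting at 0) of 8 genes in 3 control and 3 knockout libraries, with circles, squares and triangles for replicates 1, 2 and 3 and black bars for the group mean and SD. Foxp4, Adipoq and C1qa are lower in every knockout than in every control, Mb, Ppargc1a and Elovl3 are higher in every knockout, and the groups overlap in Ucp1 and Dio2.

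Genes of the brown and beige thermogenic programme had higher values in the knockouts, without any single one passing over all genes tested. Ucp1 (chromosome 8, 83290352 to 83298452, plus strand), the uncoupling protein of thermogenic mitochondria, stood at 800, 1333 and 2007 FPKM in controls and at 2898, 3009 and 1875 FPKM in knockouts. Its log2 fold change was 0.98 (SE 0.34, adjusted p = 0.15 in limma), and 1 knockout lay below the highest control. Without control replicate 1 it was 0.63. Dio2, which activates thyroid hormone, had a mean of 3.13 ± 1.81 FPKM in controls and 11.9 ± 5.89 FPKM in knockouts (SD, n = 3), also with overlapping groups. Ppargc1a, a coactivator of mitochondrial biogenesis, had 6.37 ± 1.43 and 15.0 ± 5.01 FPKM, and Elovl3, a fatty acid elongase induced by cold, had 76.0 ± 29.5 and 186 ± 66.0 FPKM, both without overlap. The fitted log2 fold changes of these genes were 1.59 for Dio2, 1.10 for Ppargc1a and 1.30 for Elovl3, with adjusted p of 0.11, 0.082 and 0.10 in limma. Smaller fitted values were found for Cox7a1 (0.79), Cidea (0.49), the beta-3 adrenergic receptor gene Adrb3 (0.20) and the beige regulator Prdm16 (0.08). Without control replicate 1, Cox7a1 had 0.34 and Cidea 0.20, without control replicate 3 Adrb3 had 0.045, and Prdm16 ranged from 0.0010 to 0.20 when 1 library was left out. The potassium channel gene Kcnk3 (0.79) and Ppargc1b (0.66) had the smallest p-values of the whole list (adjusted p = 0.070 and 0.077 in limma).

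All 24 members of the thermogenic list were tested: 17 were higher and 0 lower at an unadjusted p of 0.05, 0 passed over all genes tested and 14 passed when adjusted over the list alone. The median log2 fold change of the list was 0.70, and 0.38 without control replicate 1. The list was called higher by camera at its preset correlation of 0.01 (adjusted p = 1.9e-12), and the call was lost with an estimated correlation (adjusted p = 0.47) and with fry (adjusted p = 0.21). Over all 29 lists tested, camera at the preset called 13, of which 10 were higher and 3 lower. Camera compares a list with the other genes tested, whose median lay below 0, so a list can be called higher with a median near 0. With an estimated correlation 0 were called and 3 had an unadjusted p under 0.05, and fry called 1. The preset test also called up to 18 lists when the same 6 libraries were divided in other ways, each with both genotypes on either side, so that its calls are given here beside the estimated-correlation p.

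Secreted factors of thermogenic fat went both ways. Of 13 members tested, 4 were higher and 2 lower at an unadjusted p of 0.05 and adjusted over the list alone, and camera did not call the list (adjusted p = 0.16), though it did without knockout replicate 1 (0.034, and 0.61 with an estimated correlation). Mean FPKM in controls and knockouts was 0.51 and 3.22 for Bmp8b, 7.61 and 23.6 for Kng2, and 1.70 and 5.52 for Fgf21, each without overlap between groups. Pltp, a phospholipid transfer protein, was lower in every knockout, at 48.4 against 65.6 FPKM. Kng2 lies beside Adipoq on chromosome 16. In the list for creatine and calcium cycling, 3 of 8 tested members were higher and 1 lower at an unadjusted p of 0.05, and 0 passed when adjusted over the list alone. Camera called it higher (median 0.48, adjusted p = 0.033, and adjusted p = 0.53 with an estimated correlation), a call lost without control replicate 2 (adjusted p = 0.11) and without knockout replicate 2 (0.057), and with all 6 libraries under median-of-ratios scaling (0.11), upper-quartile scaling (0.082) and a filter at 5 FPKM (0.059). Its members Atp2a1 (3.09 and 12.5 FPKM) and Ckmt2 (0.66 and 1.99 FPKM), chosen after values were seen, are also genes of skeletal muscle, whose markers varied between libraries. Without these 2 genes the list was not called (median 0.23, adjusted p = 0.15). Its member Ckb, a creatine kinase gene, had means of 17.9 FPKM in controls and 31.0 FPKM in knockouts, and the calcium pump gene Atp2a2 had 39.0 and 47.0 FPKM, while Gatm, of creatine synthesis, had 4.81 and 3.16 FPKM.

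Most nuclear genes of the respiratory chain and of the tricarboxylic acid cycle had small positive fold changes, though many did not reach an unadjusted p of 0.05. Of 75 nuclear subunit genes tested, 71 had a positive log2 fold change and 27 were higher at an unadjusted p of 0.05, with 0 passing when adjusted over the list alone. The list median was 0.28 (camera adjusted p = 1.2e-21, and adjusted p = 0.53 with an estimated correlation). Cytochrome c (Cycs) had 133 ± 15.4 FPKM in controls and 193 ± 24.0 FPKM in knockouts (SD, n = 3), and Cox5a had 50.5 ± 3.83 and 66.9 ± 6.90 FPKM. Of the 20 tricarboxylic acid cycle genes, 9 were higher at an unadjusted p of 0.05 and 5 when adjusted over the list alone, with a median of 0.31 (camera adjusted p = 1.6e-09, and adjusted p = 0.53 with an estimated correlation). Citrate synthase (Cs) had 256 ± 22.4 and 331 ± 16.5 FPKM, and Idh3a had 174 ± 23.7 and 256 ± 29.0 FPKM. The 12 tested genes of the mitochondrial genome were not called (adjusted p = 0.12), though called higher without control replicate 2 (0.032, and 0.76 with an estimated correlation) and without control replicate 3 (0.0062, and 0.50): mt-Co1 had nearly equal means of 25992 and 26010 FPKM, whereas mt-Nd1 had 9488 and 13898 FPKM without overlap. Within this list mt-Atp6 stood at 125 FPKM in controls, far below mt-Co1, and mitochondrial genes have nuclear copies that can share their reads, so such values are uncertain. Regulators of mitochondrial biogenesis had a median of 0.08 over 13 genes, 8 above 0 and 5 below, against a median of -0.082 over all genes tested. Of the 13, 2 were higher at an unadjusted p of 0.05 and 1, Esrra, when adjusted over the list alone (camera adjusted p = 0.0062, and adjusted p = 0.60 with an estimated correlation). This call was lost without knockout replicate 2 (adjusted p = 0.055), and its median ranged from 0.021 to 0.13 in fits without 1 library, lowest without control replicate 1. Fatty acid oxidation genes had a median of 0.24, with 4 of 26 higher and 1 lower at an unadjusted p of 0.05 and 0 when adjusted over the list alone (camera adjusted p = 7.7e-07, and adjusted p = 0.53 with an estimated correlation). Without control replicate 1 the medians were 0.16 for the respiratory chain, 0.19 for the tricarboxylic acid cycle and 0.092 for fatty acid oxidation, which was 0.16 without knockout replicate 2.

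In the fit of unscaled FPKM with all 6 libraries and the filter at 1 FPKM, glycolytic genes were the only list that fry called as well as camera. Fry called 2 lists under median-of-ratios scaling and 2 with voom on the recovered reads. Cholesterol synthesis (fry adjusted p = 0.052) and macrophage markers (0.053) narrowly missed the threshold in the unscaled fit. Fry called both without a filter (0.024 and 0.044) and without the lymph node, muscle, epithelial and erythroid genes (0.045 and 0.048). Of 17 genes of glucose uptake and glycolysis, 13 were higher and 0 lower at an unadjusted p of 0.05 and 12 were higher when adjusted over the list alone, with a median log2 fold change of 0.44. Camera called the list at the preset (adjusted p = 1.9e-12), fry called it too (adjusted p = 0.031), and the call was lost with an estimated correlation (adjusted p = 0.17). The fry call was lost under upper-quartile scaling and in each fit without 1 library except the one without control replicate 1. Hexokinase 2 (Hk2) had 45.1 ± 9.79 FPKM in controls and 75.2 ± 7.08 FPKM in knockouts, Pgk1 had 180 ± 16.5 and 268 ± 23.0 FPKM, and Pgam1 had 190 ± 23.5 and 275 ± 18.9 FPKM (SD, n = 3). Skeletal muscle is rich in glycolytic transcripts, and its markers also had a positive median (1.09). When 1 library was left out the glycolytic median ranged from 0.37 to 0.49 and the muscle median from 0.35 to 1.86. Pgk1 was at 256 FPKM in knockout replicate 1, with Acta1 at 8.06 FPKM, and at 161 FPKM in control replicate 1, with Acta1 at 25.6 FPKM. These are values of 1 gene in 2 libraries, and a muscle share in the glycolytic list was not tested. Gapdh, at 43.7 and 60.8 FPKM, is uncertain because it has many processed copies in the genome. Of 19 genes of cholesterol synthesis, 8 were higher and 1 lower at an unadjusted p of 0.05, as many as when adjusted over the list alone, with a median of 0.38 (camera adjusted p = 5.4e-08, and adjusted p = 0.17 with an estimated correlation). The hydroxymethylglutaryl-CoA synthase gene Hmgcs1 had 51.4 ± 13.8 and 94.0 ± 9.05 FPKM, and Cyp51 had 11.9 ± 1.68 and 19.8 ± 3.34 FPKM. Lipogenic genes had a median of 0.27, with 7 of 21 higher and 0 lower at an unadjusted p of 0.05 and 4 higher when adjusted over the list alone (camera adjusted p = 2.2e-07, and adjusted p = 0.46 with an estimated correlation). Scd2 had 143 and 248 FPKM and glycerol-3-phosphate dehydrogenase Gpd1 had 1225 and 1906 FPKM. In the list of lipolysis and lipid droplet proteins, which camera did not call (adjusted p = 0.34), the droplet protein gene Plin2 stood at 291 ± 26.1 FPKM in controls and 517 ± 51.8 FPKM in knockouts, and passed when adjusted over the list alone.

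**Figure D2:**
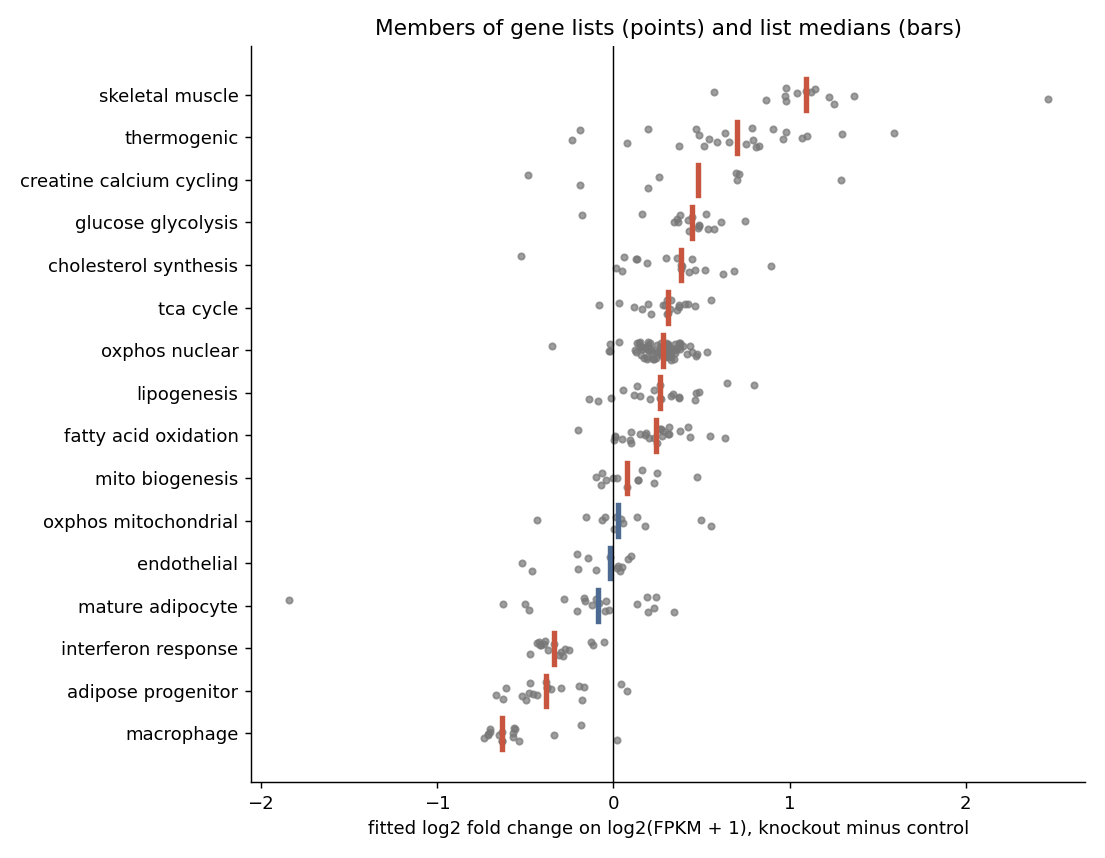
Fitted log2 fold change on log2(FPKM + 1), knockout minus control (x axis), of each tested member (grey points) of 16 gene lists, with the list median as a bar. Red bars mark the 13 lists called by camera at the preset correlation of 0.01, and blue bars mark 3 lists that were not called. The macrophage median lies at -0.63, the endothelial median at -0.016 and the thermogenic median at 0.70.

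Macrophage markers were lower in the knockouts. Of 17 tested, 15 were lower and 0 higher at an unadjusted p of 0.05 and also when adjusted over the list alone, with a median log2 fold change of -0.63 (camera adjusted p = 2.2e-07, and adjusted p = 0.47 with an estimated correlation). The complement gene C1qa had 130 ± 21.8 FPKM in controls and 79.2 ± 5.90 FPKM in knockouts (SD, n = 3), lysozyme (Lyz2) 266 ± 27.5 and 164 ± 34.3 FPKM, Cd68 24.2 ± 3.10 and 14.2 ± 2.41 FPKM, and Cd14 11.3 ± 0.60 and 6.53 ± 0.47 FPKM. Trem2, chosen after its values were seen, had 2.86 and 2.90 FPKM. Adipose progenitor and fibroblast markers had a median of -0.38, with 8 of 19 lower and 0 higher at an unadjusted p of 0.05 and 4 lower when adjusted over the list alone (camera adjusted p = 0.0031, and adjusted p = 0.64 with an estimated correlation), and the median was -0.19 without control replicate 3. Efemp1 had 57.4 ± 14.0 and 36.7 ± 1.62 FPKM, and decorin (Dcn) had 171 ± 24.3 and 124 ± 4.60 FPKM. Interferon-stimulated genes had a median of -0.34, with all 17 tested members below 0, 7 of them lower at an unadjusted p of 0.05 and 0 when adjusted over the list alone (camera adjusted p = 0.0037, and adjusted p = 0.62 with an estimated correlation). Ifit3 had 10.1 and 6.91 FPKM.

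Markers of mature adipocytes were not called as a list (adjusted p = 0.88), with 2 of 20 higher and 5 lower at an unadjusted p of 0.05 and 3 lower when adjusted over the list alone. Adipoq had 1212 ± 69.0 FPKM in controls and 872 ± 56.9 FPKM in knockouts (SD, n = 3; log2 fold change -0.48, adjusted p = 0.085 in limma). Adipsin (Cfd) had 6162 ± 420 and 4000 ± 420 FPKM, and Nnat had 183 ± 97.6 and 44.3 ± 3.30 FPKM, while Fabp4 had 2539 ± 274 and 2483 ± 42.1 FPKM. Leptin (Lep) varied widely within both groups, at 92.2 ± 77.4 and 70.1 ± 36.2 FPKM.

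Of the other cell types, skeletal muscle markers varied widely between libraries. The muscle actin gene Acta1 stood at 25.6, 6.33 and 18.1 FPKM in controls and at 8.06, 28.9 and 103 FPKM in knockouts. The 13 tested markers had a median of 1.09, Mb included, and 1 of them, Mb, was higher at an unadjusted p of 0.05, over all genes tested and when adjusted over the list alone (camera adjusted p = 6.1e-06, and adjusted p = 0.53 with an estimated correlation). The median was 0.35 without knockout replicate 3, 0.66 without control replicate 2 and 1.86 without knockout replicate 1. Neutrophil, mast cell and eosinophil markers were all below 0, with 4 of 9 lower at an unadjusted p of 0.05 and 0 when adjusted over the list alone (median -0.54, camera adjusted p = 0.062). The list was called without control replicate 1 (adjusted p = 0.0089), control replicate 3 (0.025), knockout replicate 1 (0.047) or knockout replicate 3 (0.029), and with all 6 libraries under median-of-ratios (0.010) and upper-quartile scaling (0.020). With an estimated correlation the adjusted p in these fits was 0.42 to 0.61. Fry called this list without control replicate 1 (adjusted p = 0.012), and did not in the unscaled fit of all 6 libraries (0.13). Endothelial markers such as Cldn5 (42.0 and 42.6 FPKM) were not called, with 2 of 13 lower and none higher at an unadjusted p of 0.05 and 0 when adjusted over the list alone (median -0.016, adjusted p = 0.90). Without control replicate 3 they were called higher (median 0.19, adjusted p = 0.018, and adjusted p = 0.48 with an estimated correlation). Nor were mural cells (median -0.24, adjusted p = 0.83), Schwann cells and nerve (median -0.25, adjusted p = 0.34) or red blood cells (median -0.41, adjusted p = 0.40), whose markers Acta2, Scn7a and Hbb-bs had control means of 16.3, 22.5 and 727 FPKM. When adjusted over the list alone, 0 of 8, 1 of 9 (lower) and 0 of 6 members passed, and the Schwann list was called lower without knockout replicate 1 (median -0.41, adjusted p = 0.049, and adjusted p = 0.65 with an estimated correlation). Other medians without 1 library were -0.071 (control replicate 3) and -0.47 (control replicate 2) for mural cells, -0.42 (control replicate 2) for Schwann cells, and -0.099 (control replicate 1), -0.16 (knockout replicate 1) and -0.61 (knockout replicate 3) for red blood cells. Lymphocyte markers were near the lower limit, with Cd79a, at 0.36 to 1.24 FPKM over the 6 libraries, as the only one of 20 that was tested. Of 21 epithelial markers 3 were tested, and the list was not called by camera (adjusted p = 0.89). Esr1, the estrogen receptor gene, was lower in every knockout at 7.19 and 4.70 FPKM (adjusted p = 0.14 in limma), and Krt10 had 1.32 and 1.64 FPKM. At an unadjusted p of 0.05, 1 was lower, and 0 passed when adjusted over the list alone.

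**Figure D3:**
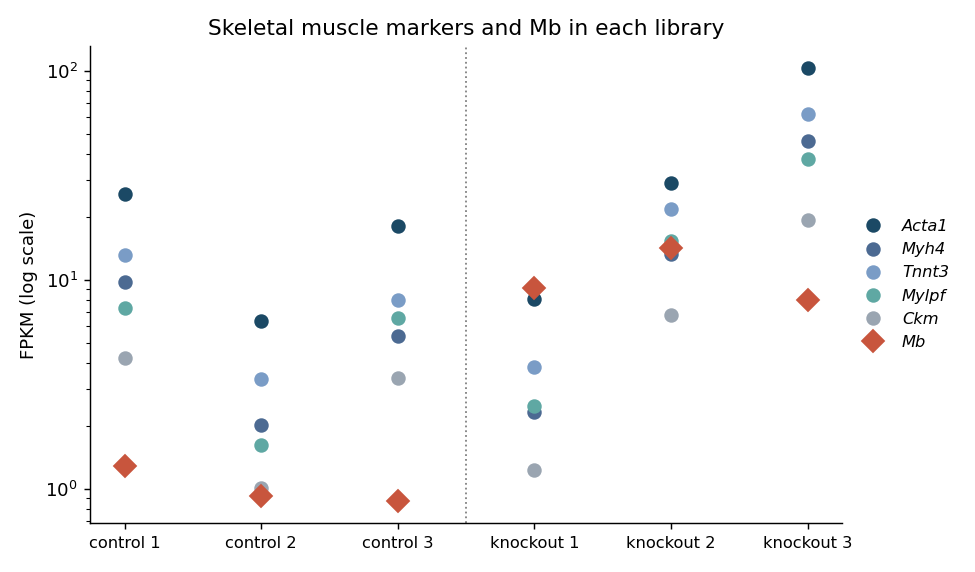
FPKM (y axis, log scale) of 5 skeletal muscle markers (circles) and of Mb (red diamonds) in each of the 6 libraries. Acta1 ranges from 6.33 FPKM in control replicate 2 to 103 FPKM in knockout replicate 3, whereas Mb lies between 0.87 and 1.28 FPKM in the controls and between 7.97 and 14.2 FPKM in the knockouts.

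The remaining lists were not called by camera with all 6 libraries and the filter at 1 FPKM. Without control replicate 3 it called cell cycle (adjusted p = 0.0055), immediate early and heat shock (0.0062) and extracellular matrix genes (0.025) higher. Without control replicate 2 it called branched-chain amino acid breakdown (0.018), at a median of 0.021 against -0.11 over all genes in that fit. Cell cycle genes were also called higher without knockout replicate 1 (0.049), without knockout replicate 3 (0.029) and without a filter (0.033). With an estimated correlation none of these calls held, with adjusted p of 0.48 to 0.81 in the same fits. Circadian clock genes went both ways, with 4 of 15 above 0 and 11 below. At an unadjusted p of 0.05, 3 were higher and 5 lower, and 2 were higher and 4 lower when adjusted over the list alone (median -0.49, adjusted p = 0.55, and median -0.26 without control replicate 1). A directional test such as camera has little power for a list whose members move in opposite directions. Nfil3 had 3.34 ± 0.85 FPKM in controls and 6.27 ± 0.22 FPKM in knockouts, and Nr1d2 had 23.1 ± 2.34 and 15.8 ± 1.64 FPKM (SD, n = 3). Among genes of branched-chain amino acid breakdown (adjusted p = 0.23), Bckdhb had 66.8 ± 5.60 and 114 ± 9.89 FPKM and was the only one of 18 to pass when adjusted over the list alone. Among endoplasmic reticulum stress genes (adjusted p = 0.35), 1 was higher and 1 lower when adjusted over the list alone: Ddit3 had 5.23 and 8.03 FPKM and Pdia4 had 29.9 and 20.3 FPKM. Among immediate early and heat shock genes (adjusted p = 0.34), Hsph1 had 3.55 and 6.38 FPKM and was the only one of 15 to pass when adjusted over the list alone. Extracellular matrix genes (adjusted p = 0.70) had 0 of 25 pass when adjusted over the list alone, with Fbln1 at 6.88 and 4.99 FPKM. Cell cycle genes (adjusted p = 0.17) had 0 of 11 pass, with Tyms at 0.80 and 1.20 FPKM.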

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

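Under the alternatives the direction of Foxp4, Ucp1 and the thermogenic median held, whereas counts near 0 or 1 moved. The call of Mb, and with it the counts of 1 changed and 1 higher gene, became 0 changed and 0 higher without a filter (more genes tested), with the recovered reads in voom, and without the lymph node, muscle, epithelial and erythroid lists, which hold Mb. Both counts became 2 with a filter at 5 FPKM (Mb and Gsta4), and at an adjusted p of 0.10 they were 591 changed, 191 higher and 400 lower genes, and 0 to 311 changed when 1 library was left out. The voom fit, the 5 FPKM filter and the 0.10 threshold were chosen after seeing the data. With a replicate block 0 genes were changed and 0 higher, with 2218 genes at an unadjusted p under 0.05 in limma. The labels do not say that same-numbered samples form pairs. Their deviations from the group means had correlations of 0.06, 0.03 and -0.25. With 3 samples per group these values cannot show whether a pairing or shared batch exists. Leaving out each library gave 0 to 5 changed, 0 to 2 higher and 0 to 3 lower genes: 0 changed without control replicate 1 and without knockout replicate 1, 5 without control replicate 3, 3 without knockout replicate 3, and 1, Nnat, which was lower, without control replicate 2. In those fits 11 to 19 lists were called, the thermogenic median was 0.38 to 0.83, Foxp4 -1.16 to -0.95 and Ucp1 0.63 to 1.30. Camera with an estimated correlation called 0 lists and fry called 1, and the thermogenic median of 0.70 then no longer passed (adjusted p 0.47 and 0.21). Mb lost its call in 6 of 13 alternatives, with log2 fold changes of 2.24 to 3.29 and adjusted p of 0.024 to 0.17. The endothelial median turned positive without a filter (0.021), with median-of-ratios scaling (0.064), with upper-quartile scaling (0.040) and without control replicate 3 (0.19), with a range of -0.18 to 0.19 when 1 library was left out. Fabp4, uncalled and near 0, turned to 0.072 and 0.043 under the same scalings. With 1 library left out it ranged from -0.11 to 0.040, Cldn5 from -0.18 to 0.37, Lep from -0.86 to 0.58, Trem2 from -0.11 to 0.092, mt-Co1 from -0.11 to 0.12 and St6gal1 from -0.32 to 0.048. Unless a cause is given, the cause was not tested. Planned count models and their size factors, and the filter in CPM, were not run. Of the models for counts, only voom was run on recovered reads. Depth limits the low genes most: Mb had as few as 20 reads in a control.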

Other observations

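Among single genes with non-overlapping groups that passed only an adjusted p of 0.10, a threshold and choice of genes made after the data were seen, some stand outside the lists of the report. Mean FPKM in controls and knockouts was 7.40 and 30.2 for the guanosine monophosphate reductase gene Gmpr, 0.67 and 4.36 for the elongation factor gene Eef1a2, 7.71 and 19.8 for the aspartate aminotransferase gene Got1, and 5.24 and 13.3 for the copper ferroxidase family member Hephl1. Lower values in every knockout were found for the imprinted gene Peg3 (9.50 and 3.39 FPKM), the pantetheinase gene Vnn1 (4.92 and 1.40), Wfdc17 (20.6 and 8.10), the cytochrome P450 gene Cyp2e1 (590 and 264) and the sialyltransferase gene St3gal6 (9.11 and 3.62). The glutathione transferase gene Gsta4 came next to Mb in rank of p, at 31.6 ± 1.10 FPKM in controls and 55.6 ± 2.30 FPKM in knockouts (SD, n = 3), with an adjusted p of 0.055 in limma.

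Of the clock genes, none of which passed over all genes tested in limma, Per3 had 9.13 ± 3.70 and 3.83 ± 1.46 FPKM with overlapping groups (adjusted p = 0.14), and Cry2 had 9.46 ± 1.08 and 6.81 ± 0.61 FPKM in controls and knockouts (SD, n = 3), while Nfil3 had 3.34 and 6.27 FPKM. Chosen after values were seen, Arntl (0.62), Clock (0.32) and Cry1 (0.40) had positive log2 fold changes, as did Nfil3 (0.76). The other 11 clock genes tested were below 0, with Per3 (-1.03) and Dbp (-1.02) the lowest. The hour of dissection is not in the labels, so a difference in hour between the groups cannot be told apart from genotype.

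All tests in the paragraphs that follow were chosen after the results were seen. The first pattern is the higher Mb value together with variable skeletal muscle markers. The 12 tested skeletal muscle markers other than Mb moved in step from library to library. The median SD of their log2 ratio to Acta1 was 0.26 times the SD of log2 Acta1. Of these markers, 0 of 12 lay higher in all knockouts than in all controls. Pieces of muscle in some libraries could give such a pattern. Mb did not follow: after the most that muscle could bring at the lowest ratio of Mb to Acta1 was taken off, the lowest knockout still held 2.97 FPKM, above the highest control at 1.28 FPKM as measured. Pieces of muscle of like composition are thus argued against as the whole source of Mb, while muscle with more myoglobin in the knockouts, or expression of Mb in thermogenic adipocytes, stays open and was not tested.

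The second pattern lies around Adipoq on chromosome 16. Within 150 kb of Adipoq (23146536 to 23158028), Kng2, Eif4a2 and Rfc4 had log2 fold changes of 1.59, 0.36 and 0.70 and were higher in every knockout, St6gal1 had -0.17, and Kng1, below the expression filter, had 1, 0 and 0 reads in controls and 30, 31 and 20 reads in knockouts. Reads shared with its paralog Kng2 are argued against for Kng1, since at the knockout ratio 28.0 Kng1 reads were due in controls and 1 was found (two-sided Fisher exact test, p = 1.4e-09, counting error only). Extra copies of this region in the Cre driver line and thermogenic activation of the neighbours cannot be told apart. Of the 4 tested neighbours 3 were higher in every knockout, but the region was chosen because of them, and the labels list the driver only for knockouts. Eif4a2 (plus strand, to 23114136) and Rfc4 (minus strand, from 23113943) also overlap. The strand setting of the counting is not given, so these 2 genes may share reads. With the thermogenic list mean as a covariate the mean difference of all 4 tested neighbours went from 0.62 to 0.17, with a 95% interval of -0.47 to 0.81. This fit cannot decide, since the interval holds both 0 and 0.62. The thermogenic mean itself followed genotype, at 4.53 to 5.18 in controls and 5.39 to 5.82 in knockouts, and Kng1 was not in the fit.

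The third pattern is the lower macrophage markers. A smaller share of RNA from all cells other than adipocytes cannot be told apart from a change in macrophages alone. Beside the macrophage median of -0.63 the medians were -0.54 for neutrophils, mast cells and eosinophils, -0.41 for red blood cells, -0.38 for progenitors, -0.25 for Schwann cells, -0.24 for mural cells and -0.016 for endothelial cells, and the last was 0.19 without control replicate 3. The mean of macrophage markers fell by 0.45 more than that of endothelial markers, with a 95% interval of -0.94 to 0.040 for the difference, so 0 was not excluded. This was the largest of the differences computed. Macrophage minus other means gave -0.37 for Schwann cells, -0.37 for mural cells and -0.19 for progenitors. It gave -0.15 for red blood cells and -0.022 (-0.56 to 0.51) for neutrophils, mast cells and eosinophils, and each of these intervals held 0. Whether there were fewer macrophages, or macrophages with lower marker expression, as hypotheses, was not tested, and Trem2 had nearly equal means of 2.86 and 2.90 FPKM.

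The 6 libraries can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. The real division gave 1 changed gene and the highest other 1, a count that 2 of 10 divisions reached. It gave 2601 genes with an unadjusted p under 0.05 and the highest other 859, and 1 of 10 reached that many. It gave 13 lists called at the preset correlation and the highest other 18, with 7 of 10 reaching as many. The thermogenic median was 0.70 and the highest other in size 0.50, with 1 of 10 as far from 0. Each other division sets 2 samples of one genotype and 1 of the other against the rest, so part of any genotype difference can remain in it.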
